A study of Arabidopsis thaliana with 3 samples.

How the data were processed

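Total RNA of whole seedlings was measured on 3 Affymetrix arrays with 8297 probe sets, 1 each for wild type, ppi1 and line 75-IV. Per the labels' protocols, RNA was checked on a Bioanalyzer, reverse transcribed from an oligo-dT primer with a T7 promoter and transcribed into biotin-labelled cRNA. Priming at the 3' end makes probe sets near the 5' end depend on the integrity and the yield of long transcripts. The number of plants pooled per sample is blank in the series' design field. The deposited values are signals on a linear scale, 1 per probe set, never negative. Per the labels, each array was read over 285156 cells with the background and noise values given in the report. The software that made the signals and its scaling target were not given in the sources used here.

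The means of the deposited signals, trimmed by 2%, were 100.178, 100.168 and 100.176, within the preset tolerance of 2%. The table was therefore taken as already scaled and was used as deposited, on the log2 scale. Such scaling sets the average of the arrays equal, so a difference in total mRNA between seedlings could not appear, and a few changed abundant transcripts can shift all other ratios. The 50 control probe sets were left out of gene results. Signals below the 40th percentile of all values (14.9) were raised to that floor. A gene was measured in a comparison if it lay above the floor on both arrays, and a gene above it on 1 array only was counted apart and not ranked. The median signal was 22.1 in wild type, 26.3 in ppi1 and 24.2 in line 75-IV. Saturation at the upper end, where several photosynthesis genes lie, was not tested.

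Probe sets were named with the platform annotation, in which 3794 had 1 gene, 70 several and 4433 none listed, 4383 of them without the controls. Probe sets with several genes or none entered no gene result. Of the 3602 genes, 3592 were found in the RefSeq gene table, and 164 had more than 1 probe set, of which the brightest by mean log2 signal was used. The annotation and the arrays gave no genome build, so no coordinates are printed.

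Log2 ratios were computed for each pair of arrays, and genes at least 2-fold apart were counted, which is a rule of size and no test. With 1 array per group no p-value or standard error was computed. Gene lists were fixed before the data were examined, 21 lists with 423 entries, of which 44 had a named probe set. No probe set was named for the lists of plastid import and chaperones, plastid-encoded genes, dark and starvation genes, root markers and reference genes. DFR and ICL, the single entries covered for flavonoid and seed reserve genes, were below the floor throughout, and of the defence genes THI2.1 was below it throughout and LCR67 above it in line 75-IV only. For lists with at least 5 measured members, the median log2 ratio was given with a bootstrap 95% interval over members (2000 draws). Its percentile among 10000 random lists of the same size, matched on mean level in 20 bins, describes these arrays and is no test. The genes named were set by a rule fixed beforehand. It took the 12 highest and the 12 lowest ratios of each comparison, the targeted genes, up to 3 genes with the largest bounds, which none met, and in each list up to 4 members with the largest ratios. Names outside this rule are those of the 12 genes shared by both mutants, AT1G53540 and members of lists described in the closing section, which were chosen after their values were seen. Ratios were also looked at by chromosome, which was not carried further and is not used here.

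The correlation of both mutants' ratios was set beside 200 simulated pairs of unchanged arrays that share a control, with the noise of line 75-IV against wild type, the pair of least spread, given to all 3 arrays. Since the ppi1 ratios spread more, a simulation with the variance component of each array as its own noise was added after seeing the data. These components hold any real difference as well as noise, and they fix the simulated r. The alternatives fixed beforehand were median centring, quantile normalization, loess on level (span 0.4), floors at the 20th and 60th percentile or none, the median over probe sets, probe sets without a cross-hybridisation suffix, thresholds of 1.5-fold and 3-fold, other matching of the random lists, and lists without their farthest member. Scaling to the bacterial spike-in controls (9 probe sets), wider gene lists, all probe sets, and only signals of at least 4 times the floor were chosen after seeing the data. For the wider lists this was the coverage of the annotation and the control probe sets, and no gene's ratio had been examined.

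The procedure was tested on simulated arrays made from the real signals of 3602 genes. Each change was given to 50 genes. Shares were taken over changed genes that stayed above the floor on both simulated arrays, with the same probe set. All 50 genes raised by 4-fold stayed so, but of those lowered by 4-fold 30, 28 and 23 did, in the order of the comparisons below. The others were not counted. For ppi1 against wild type, all measured genes changed by 4-fold were counted as 2-fold, 42% of those raised by 2-fold and 3.18% of unchanged genes. For line 75-IV against wild type the shares were 100%, 46% and 0.282%. For ppi1 against line 75-IV they were 98% (100% of those lowered), 58% and 3.23%. Lists of 13 genes shifted by -0.4 fell outside the central 95% of random lists in 69%, 96% and 72% of simulations, and unchanged lists in 2%, 2% and 4.5%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.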

Results

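Transcript levels were measured in whole Arabidopsis thaliana seedlings of the Col-0 background at growth stage 1.02, grown in 16 h of light and 8 h of dark on medium with 0.5% sucrose. The 3 groups were wild type, the plastid protein import mutant ppi1, which carries a T-DNA in the gene for Toc33, and a line called 75-IV, labelled as a T-DNA insertion in a Toc75 gene. Toc33 is a receptor and Toc75 proteins form the channel of the translocon through which proteins made in the cytosol enter plastids. The series title calls the second mutant ppi3, and the label of line 75-IV prints the locus AT4G09070, whereas the gene table used here gives TOC75-IV as AT4G09080, so the line is named 75-IV throughout. Each group had 1 array, so there were no replicates, no test was possible, and every difference is a difference between arrays whose number limits the precision.

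Signals were read on 8297 probe sets per array and had trimmed means of 100.2 on each of the 3 arrays. The scanner's background was 50.5 in wild type, 62.0 in ppi1 and 56.6 in line 75-IV. Its noise value was 1.65, 2.49 and 1.94 in the same order, and 11, 504 and 20 of 285156 cells were marked as outliers. Of 3602 named genes, 1953 lay above the floor of 14.9 in wild type, 2086 in ppi1 and 2006 in line 75-IV. The control probe sets for glyceraldehyde-3-phosphate dehydrogenase (GAPDH) differed along the transcript. At its 5' end the signal was 75.2 in wild type, 787.9 in ppi1 and 940.5 in line 75-IV, against 1408.9, 1268.8 and 2275.0 at its 3' end. The ratio of the 3' to the 5' signal was therefore 18.7 in wild type, 1.61 in ppi1 and 2.42 in line 75-IV, while for ubiquitin it was 4.16, 2.75 and 3.51. The mutated genes could not serve as a check of the labels, because TOC33 (AT1G02280), TOC75-IV, AT4G09070 and TOC34 (AT5G05000) had no probe set named for them alone in the annotation and were not analysed here.

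**Figure D1:**
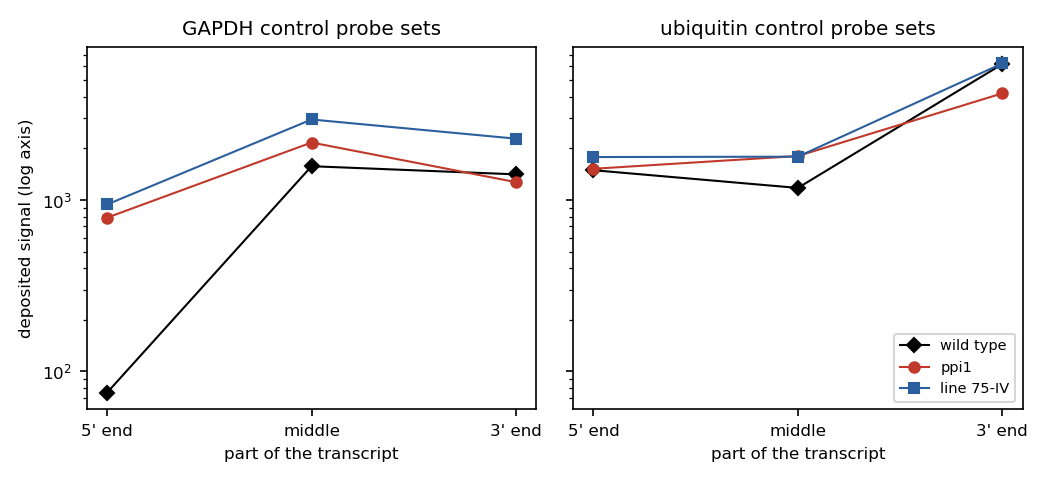
Deposited signal (log axis) of the control probe sets for the 5' end, the middle and the 3' end of the GAPDH and ubiquitin transcripts, with 1 point per array for wild type, ppi1 and line 75-IV. The wild-type signal at the 5' end of GAPDH was 75.2, against 787.9 in ppi1 and 940.5 in line 75-IV.

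The comparison of ppi1 with wild type asked how the seedling transcriptome differed when Toc33 was disrupted. All 13 measured genes of the fixed photosynthesis lists had lower signals in the ppi1 array than in the wild-type array, though 4 of 13 when the arrays were scaled to spike-in controls. That scaling used the mean log2 ratio of these controls, -0.48 in ppi1 against wild type. The brightest controls differed by only -0.12, -0.21 and -0.25, so it moved bright genes by more than bright controls differed. Whether the controls follow the amount of mRNA was not tested. Of 12 more photosynthesis genes in a list added later, 4 were higher in ppi1, FIB, a plastid lipid-associated protein, by 2.31-fold, and their median was -0.08 (0.41 under the spike-in scaling). PSAN, a subunit of photosystem I, had a signal of 1628.9 in ppi1 and 3755.6 in wild type, 2.31-fold lower. LHCB4.3, a light-harvesting protein of photosystem II, was 2.11-fold lower (58.9 against 124.2), and PORB, a protochlorophyllide reductase of chlorophyll synthesis, was 2.09-fold lower (90.8 against 189.9), all 3 by less than 2-fold under the spike-in scaling. The highest gene in ppi1 was AT5G64120, a class III peroxidase, at 777.7 against 115.8 in wild type, 6.72-fold higher.

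Photosynthesis genes were described with 3 lists fixed before the data were examined, for light harvesting, the photosystems with electron transport, and the Calvin cycle. Of their 81 entries, 13 had a named probe set, and the signals of all 13 were lower in ppi1. The median log2 ratio was -0.39 (bootstrap 95% interval over members -0.70 to -0.20), which lay at the 0.33 percentile of 10000 random lists matched on level. Scaling to the bacterial spike-in controls, with 1 factor per array, turned this median to 0.09. Such a factor shifts all ratios alike, so the percentile (0.26) could change only through the floor and the random draws. After quantile normalization 9 of the 13 and after loess 11 of the 13 were lower. The loess-adjusted median lay at the 2.93 percentile, just inside the central 95% of random lists. In the Calvin cycle list all 4 measured genes were lower, with 2 of 4 lower under the spike-in scaling. Phosphoribulokinase (PRK) had a log2 ratio of -0.74, the phosphoglycerate kinase AT1G56190 -0.70 and sedoheptulose bisphosphatase (SBPASE) -0.42. The 6 photosystem genes had a median of -0.29 (interval -0.81 to -0.10) at the 9.31 percentile, and the spike-in scaling turned it to 0.19. Each of the 3 light-harvesting genes was lower, with 2 of 3 lower after quantile normalization or loess and 1 of 3 under the spike-in scaling.

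Other plastid lists were thinly covered. Among 5 tetrapyrrole genes, PORB (-1.06) and the geranylgeranyl reductase AT1G74470 (-0.70) were lower. GSA1, which makes 5-aminolevulinate, was higher (0.88), as was HEMA2 (0.25). The list's median of -0.11 (interval -1.06 to 0.88) lay at the 21.5 percentile and turned to 0.37 under the spike-in scaling. Of the lists for plastid proteins outside photosynthesis, 4 genes were measured on both arrays. AT2G45300, an enzyme of the shikimate pathway, had a log2 ratio of -0.76, which was -0.10 as the median of its probe sets, and FATB, an acyl carrier protein thioesterase, had -0.52. The plastid ribosomal protein genes AT2G43030 and AT4G01310 had ratios of -0.25, above 0 under the spike-in scaling, and 0.22. With 4 members, below the minimum of 5, they could not serve as a contrast. The photosynthesis median minus theirs was -0.01 (interval -0.63 to 0.44), -0.24 as the median over probe sets, -0.40 with probe sets without a suffix and 0.24 after loess. A wider list of plastid proteins outside photosynthesis had 17 measured genes, 10 of them higher in ppi1, with a median of 0.15 at the 72.2 percentile (9 of 17 and 0.05 after median centring, 15 of 17 and 0.64 under the spike-in scaling). FaTA, another thioesterase, was above the floor in wild type and below it in ppi1. The photorespiration genes AT1G11860 and HPR had ratios of -0.26 and -0.12, 1 of which was above 0 after quantile normalization or loess and both under the spike-in scaling.

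Stress genes of the fixed lists did not move one way. SAPX and TAPX, the ascorbate peroxidases of stroma and thylakoid, had log2 ratios of -1.05 and -0.62, whereas the peroxiredoxin AT3G11630 stood at 0.04. The small heat shock protein gene AT2G29500 was 2.23-fold higher in ppi1 (33.5 against 15.0), near the floor. Another, AT1G53540, had 49.3 in ppi1 and lay below the floor on the other arrays. All 5 measured genes of cytosolic ribosomal proteins were lower, with a median of -0.29 (interval -0.59 to -0.21) at the 10.8 percentile, but with 4 of 5 higher and a median of 0.19 under the spike-in scaling. The clock gene GI had a ratio of 0.30, the histone gene HIS4 -0.08 and the lycopene cyclase gene LYC -0.36, which was 0.19 as the median of its probe sets.

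Among the genes with the lowest ratios in ppi1 was M17, a late embryogenesis abundant protein (16.9, near the floor, against 86.2, 5.10-fold lower). Others were the sucrose phosphate synthase gene ATSPS4F (28.7 against 107.8, 3.76-fold) and the expansin gene EXPA8 (91.6 against 327.9, 3.58-fold). The cold-response genes KIN2 and LTI30, a dehydrin, were 3.44-fold and 2.60-fold lower. So were the peroxidase genes AT2G38390 (3.52-fold) and AT3G21770 (2.68-fold) and the dirigent-like gene AT2G39430 (2.81-fold, with 16.0 in ppi1, near the floor). The others of the 12 lowest were AT1G03746, AT4G28080, AT2G22510 and AT2G32560, with log2 ratios of -1.94, -1.88, -1.84 and -1.61. AT2G32560 stood at -1.14 as the median of its probe sets. After AT5G64120, the highest genes were AT4G38550 (5.47-fold), AT4G32020 (5.43-fold), SGT1A, a co-chaperone of disease resistance proteins (98.8 against 18.4, 5.37-fold), NIG (5.35-fold) and the methyltransferase-like gene AT4G33110 (5.23-fold). The chitinase family gene AT2G43620 was 3.95-fold higher. AT4G39680, AT4G29020, SK18, AT2G01220 and AT4G37920 had log2 ratios between 1.77 and 1.89, and AT2G01220 stood at 0.96 as the median of its probe sets. Wild-type signals near the floor were those of AT4G38550 (19.4), SGT1A (18.4), NIG (20.8), AT2G01220 (17.5) and AT4G37920 (16.4).

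In all, 1853 genes were above the floor on both arrays, of which 79 were at least 2-fold higher and 45 at least 2-fold lower in ppi1, 6.69% together. This split followed the scaling, with 59 higher and 65 lower after median centring, 60 and 58 after quantile normalization, 49 and 61 after loess, and 367 and 12 after spike-in scaling, which moved the median of all genes from 0.11 to 0.57. A further 233 genes were above the floor in ppi1 only and 100 in wild type only, none of them at 4 times the floor or more.

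**Figure D2:**
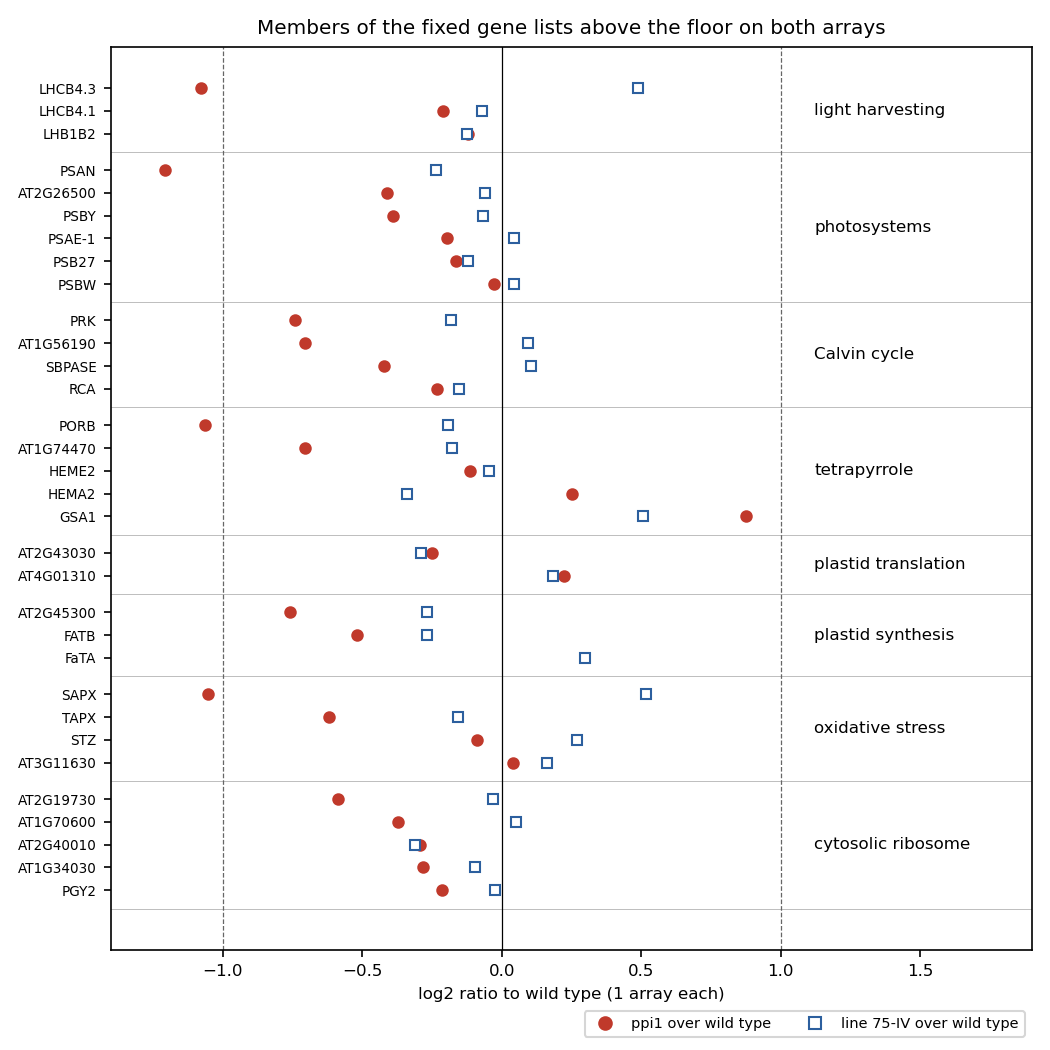
Log2 ratio to wild type (x axis) of each member of 8 fixed gene lists that was above the floor on both arrays, 1 array per group, with ppi1 as filled circles, line 75-IV as open squares and dashed lines at 2-fold. All 13 genes of the light-harvesting, photosystem and Calvin cycle lists lay below 0 in ppi1 with the deposited scaling (median -0.39; 0.09 under the spike-in scaling) and 8 of 13 in line 75-IV (median -0.07; 0.03 after quantile normalization, 0.02 after loess, -0.24 under the spike-in scaling).

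The comparison of line 75-IV with wild type asked the same question for the insertion labelled as Toc75. Fewer and smaller differences were seen. The methyltransferase-like gene AT4G33110 (155.2 against 34.7, 4.47-fold), AT4G32020 (4.18-fold) and the peroxidase gene AT5G64120 (439.0 against 115.8, 3.79-fold) were the highest. The lowest was another peroxidase gene, AT5G39580, at 70.1 against 198.2 in wild type, 2.83-fold lower. The lowest genes also included 2 enzymes that break down branched-chain amino acids. MCCA, the biotin-carrying subunit of methylcrotonyl-CoA carboxylase, was 2.23-fold lower (45.8 against 102.2). AT1G21400, a subunit of the branched-chain keto acid dehydrogenase, was 2.13-fold lower (37.5 against 79.8).

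Of the same 13 photosynthesis genes, 8 were lower and 5 higher in line 75-IV, with a median log2 ratio of -0.07 (interval -0.12 to 0.05) at the 28.4 percentile, which was 0.03 after quantile normalization and 0.02 after loess, while under the spike-in scaling 12 of 13 were lower with a median of -0.24. PSAN had a ratio of -0.23, PRK -0.18 and SBPASE 0.11, and LHCB4.3 was higher (0.49). The photosystem genes had a median of -0.06 at the 38.5 percentile (0.06 after quantile normalization, and all 6 lower with -0.24 under the spike-in scaling). Of the Calvin cycle genes 2 of 4 were higher, and none under the spike-in scaling. The 5 measured genes for plastid proteins outside photosynthesis had a median of -0.27 (interval -0.29 to 0.30) at the 4.7 percentile. The photosynthesis median minus theirs was 0.20 (interval -0.36 to 0.31; 90.6 percentile of random pairs of lists), but -0.08 as the median over probe sets and -0.25 with probe sets without a suffix. Tetrapyrrole genes had a median of -0.18 at the 6.99 percentile, with GSA1 at 0.51 and HEMA2 at -0.34. Cytosolic ribosomal protein genes had a median of -0.03 (0.02 after quantile normalization) at the 47.0 percentile. SAPX was higher (0.52) and TAPX stood at -0.16. The zinc finger gene STZ had 0.27, the heat shock gene AT2G29500 0.30, HIS4 -0.22 and GI -0.01.

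Further genes among the 12 lowest in line 75-IV were CCS, the copper chaperone of superoxide dismutase (2.12-fold lower), the autophagy gene ATG8E (857.6 against 1732.6, 2.02-fold) and the glucosyltransferase gene UGT84A3 (1.99-fold). AT4G36850, AT4G33960, AT2G05540, AT2G36690 and AT1G26920 had log2 ratios from -1.22 to -0.88. AT2G30600 had -1.11 with its brightest probe set and 0.14 as the median of its probe sets. On the higher side stood 3 pectin-modifying enzymes, namely the pectate lyases AT1G04680 (3.10-fold) and AT4G24780 (2.59-fold) and the pectin methylesterase ATPMEPCRD (2.59-fold). AT4G24780 stood at a log2 ratio of 1.37 and at 0.63 in its probe set without a cross-hybridisation suffix. AT4G29020, NIG, AT2G01220, the jacalin lectin gene AT1G52070, AT5G27120 and AFR had log2 ratios from 1.29 to 1.60. The wild-type signals of NIG (20.8), AT2G01220 (17.5) and AFR (16.7) were near the floor.

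Of 1859 genes above the floor on both arrays, 27 were at least 2-fold higher and 8 at least 2-fold lower in line 75-IV, 1.88% together, and 16 and 20 after spike-in scaling, which moved the median of all genes from 0.05 to -0.12. Another 147 genes were above the floor in line 75-IV only and 94 in wild type only.

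The direct comparison of the mutants left out the wild-type array. Expansin EXPA8 (91.6 against 479.2, 5.23-fold), the dirigent-like gene AT2G39430 (16.0, near the floor, against 83.2, 5.20-fold) and the peroxidase gene AT2G38390 (68.4 against 334.9, 4.90-fold) were the lowest in ppi1 relative to line 75-IV. Highest were the peroxidase gene AT5G39580 (410.0 against 70.1, 5.85-fold) and the chitinase family gene AT2G43620 (452.3 against 77.5, 5.84-fold). They were followed by SGT1A (98.8 against 19.7, near the floor, 5.02-fold) and MCCA (3.99-fold). Of the 13 photosynthesis genes, 12 were lower in ppi1, with a median log2 ratio of -0.33 (interval -0.56 to -0.08) at the 0.68 percentile. The spike-in scaling turned this median to 0.34. Its percentile there (0.58) stayed close by construction, as 1 factor per array shifts all ratios alike. The percentile was 2.97 after quantile normalization, 2.52 after loess and 2.55 with probe sets without a suffix, all just inside the central 95%. LHCB4.3 stood at -1.56, PSAN at -0.97 and AT1G56190 at -0.80.

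The photosystem genes alone had a median of -0.28 (0.38 under the spike-in scaling) at the 6.53 percentile. Tetrapyrrole genes had -0.07 (0.59) at the 30.0 percentile and cytosolic ribosomal protein genes -0.19 (0.47) at the 19.0 percentile. SAPX was 2.97-fold lower in ppi1 than in line 75-IV. The photosynthesis median minus that of the 4 other plastid genes measured was -0.22 (interval -0.60 to 0.25). Cold-response genes KIN2 and LTI30 were 3.59-fold and 3.57-fold lower in ppi1, IAGLU, an auxin glucosyltransferase, 3.74-fold, and the peroxidase gene AT4G30170 3.29-fold. AT1G03746, AT2G22510, ATSPS4F, AT2G07140 and AT2G23540 had log2 ratios from -2.18 to -1.74. AT3G52500, AT2G30600, AT4G38550, AT2G19310, AT4G38020, AT5G44290 and AT4G23460 were also among the 12 highest, led by AT3G52500 with 1.94. The pectin methylesterase gene ATPMEPCRB had 1.78, and 1.02 in its probe set without a suffix.

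Of 1885 genes above the floor on both mutant arrays, 52 were at least 2-fold higher and 66 at least 2-fold lower in ppi1, 6.26% together. The split was 39 and 76 after loess and 483 and 17 after spike-in scaling, which moved the median of all genes from 0.07 to 0.70. Above the floor in ppi1 only were 201 genes and in line 75-IV only 121.

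The last comparison asked whether the mutants differed from wild type in the same genes. Across 1796 genes above the floor on all 3 arrays, which are not independent replicates, the log2 ratios of both mutants had a Pearson r of 0.35 and a Spearman rho of 0.32. Because both ratios share the wild-type array, arrays without any difference also correlate, so r by itself does not show that the mutants resembled each other. Simulated unchanged arrays had an r of 0.50 with equal noise on all arrays and of 0.39 with the component of each array as its noise, or 0.34 with components from the plain SD, values that follow from the noise assumed. The covariance was 0.071 (bootstrap 95% interval 0.058 to 0.087), against a simulated 0.055 and 0.063 with noise from a robust SD. With the plain SD, which is the like measure for a plain covariance, the simulated values were 0.071 with equal noise and 0.070 with own noise. The last follows from the observed covariance by construction, so no excess was shown. Part of the observed overlap can come from the shared array, which with 1 array could not be split.

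There were 12 genes at least 2-fold higher in both mutants, where independent lists would share 1.1. The count followed the floor, with 41 at the 20th percentile and 4 at the 60th. Unchanged arrays that share the wild-type array, simulated with normal noise of its own for each array, gave a mean of 0.505, or 1.345 with the plain SD (95% of simulations 0 to 4). With equal noise, which gives ppi1 ratios less spread than observed, the means were 0.115 and 0.735. Each simulated array had normal noise of 1 size for all genes. The observed spread differed with level. For line 75-IV against wild type it was 0.46 at a mean signal of 24.5 and 0.19 at 1033.5. A count of 2-fold genes depends on the genes of largest spread, so 12 against these simulated means does not measure an excess of shared genes. By this selection every shared gene was lower on the wild-type array, the array with the GAPDH ratio of 18.7, so this is no separate observation. Among them were AT5G64120, AT4G33110, AT4G32020, NIG, AT4G29020, the pectate lyase AT1G04680 and the pectin methylesterase ATPMEPCRD. No gene was 2-fold lower in both (0.20 for independent lists, simulated means 0.525 and 1.42). One peroxidase gene, AT5G39580, was 2-fold higher in ppi1 (log2 ratio 1.05) and 2-fold lower in line 75-IV (-1.50). Solved into a component per array, the variance of the log2 differences was 0.177 for ppi1 (interval 0.157 to 0.199), 0.064 for wild type (0.047 to 0.078) and 0.047 for line 75-IV (0.033 to 0.064), which separates arrays and not genotypes.

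**Figure D3:**
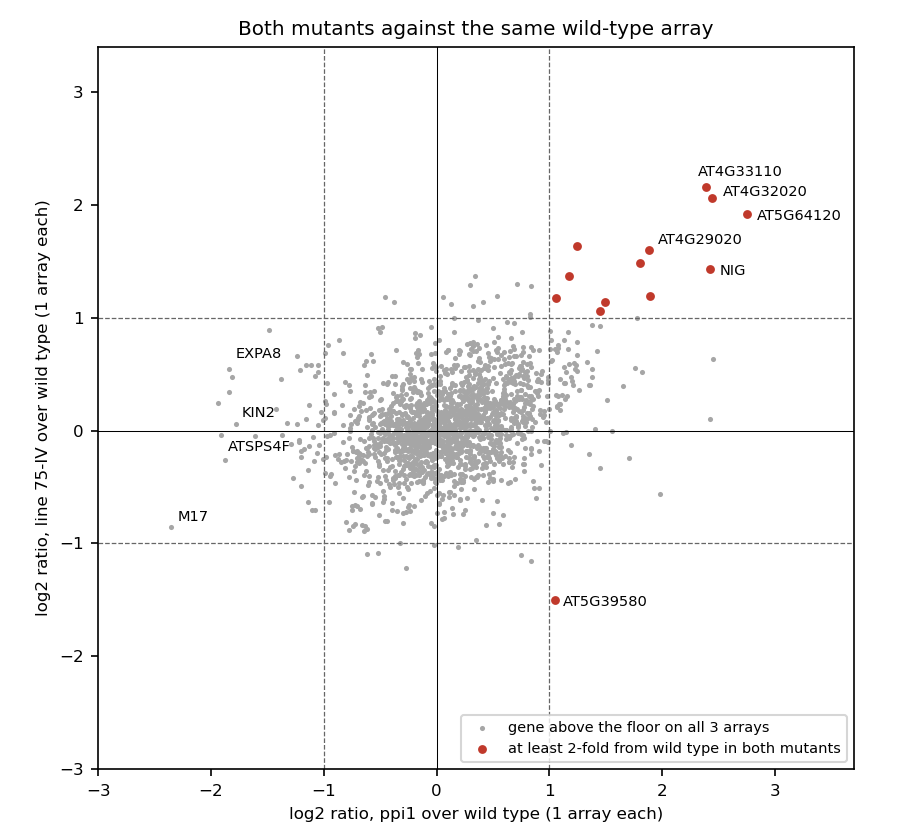
Log2 ratio of line 75-IV to wild type (y axis) against that of ppi1 to wild type (x axis) for the 1796 genes above the floor on all 3 arrays, 1 point per gene, with dashed lines at 2-fold. The 13 red points are at least 2-fold from wild type in both mutants, 12 higher in both and AT5G39580 in opposite directions, and the wild-type array enters both axes.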

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

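In this part, the tests of a level-dependent difference, of a wild-type array that stood apart and of noise between probe sets were chosen after the result was seen, as was the interval over members in the test of carbon starvation genes, without which that explanation would have been argued against. The peroxidase gene AT5G39580 was singled out because its log2 ratio to wild type was 1.05 in ppi1 and -1.50 in line 75-IV, and with 1 array per group this difference was not tested. A probe set that the annotation does not name, the highest of its kind in both mutants, had a signal of 33.4 in wild type, 1325.5 in ppi1 and 1161.4 in line 75-IV, log2 ratios of 5.31 and 5.12. The control probe set for the 5' end of GAPDH, outside the gene comparisons, had log2 ratios of 3.39 in ppi1 and 3.64 in line 75-IV.

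Photosynthesis genes of the fixed lists were lower in ppi1 than in wild type, with a median of -0.39 that the spike-in scaling turned to 0.09. Their percentile was 0.33 with the deposited scaling and 0.26 with the spike-in scaling. The second value is no separate check, since 1 factor per array shifts all ratios and random lists alike. A wild-type array that stood apart is argued against as the whole cause with the deposited scaling, but not under every setting. The comparison with line 75-IV, which leaves that array out, put the same genes at the 0.68 percentile. It put them at 2.97 after quantile normalization, 2.52 after loess and 2.55 with probe sets without a suffix. These lie just above the bound of 2.5, so this explanation was not settled. A level-dependent difference between the arrays stays open, because loess moved the percentile to 2.93, inside the central 95%, and the median to -0.21 (interval -0.62 to -0.01). Leaving out the farthest member, PSAN, moved the percentile to 2.86, and the list of further photosynthesis genes lay at the 27.0 percentile. The loss of Toc33 also remains an untested explanation, as genotype and array cannot be separated with 1 array per group.

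More genes differed by 2-fold from wild type in ppi1 (124 of 1853) than in line 75-IV (35 of 1859). Low-signal genes near the floor are argued against as the cause, since among genes at 4 times the floor 44 of 895 and 10 of 913 differed by 2-fold, a quotient of 4.4. The test of measurement noise set beforehand stayed undecided, with a correlation between separate probe sets of a gene of 0.37 (0.15 to 0.56) for ppi1 against wild type, between its bounds of 0.3 and 0.5. In the test chosen later the ratios of ppi1 to line 75-IV correlated with r = 0.75 (92 genes, interval 0.61 to 0.84) and a Spearman rho of 0.61. For these genes this argues against noise that differs between probe sets as the whole of the differences between the mutant arrays. It does not measure that noise, because r also rises with the size of the differences between genes. The robust SD of the difference between probe sets of a gene was 0.60 for ppi1 and 0.40 for line 75-IV against wild type. Between the mutants it was 0.45. A share of such noise of the ppi1 array in the larger count therefore stays open. Whether probe sets of a gene shared probes was not examined. A difference of the ppi1 sample or array common to all probe sets of a gene stays open, as does an untested effect of genotype.

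Branched-chain amino acid catabolism genes were among the lowest of line 75-IV. In a list of 12 made after MCCA, AT1G21400 and ALDH6B2 had been seen to be low, 5 of 6 measured members were lower (median -0.67, negative under each scaling), and the 4 outside the named genes, ALDH6B2 included, had a median of -0.45. A wild-type sample with more carbon starvation transcripts would lower them in both mutants. In ppi1 the 5 members outside the named genes had a median of 0.18 (interval -0.62 to 0.59), above the bound of 0 set beforehand by less than its spread, so by this test the explanation cannot be told apart from one in line 75-IV itself. The remaining ATG8 genes had medians of -0.35 in ppi1 and -0.02 in line 75-IV, whereas the prediction asked for low values in both, so it was not met in full. In ppi1 against line 75-IV, without the wild-type array, 5 of 6 members were higher. Their median was 0.56 (interval -0.09 to 1.46) at the 99.1 percentile, and 0.45 at the 94.9 percentile for the 4 outside the named genes. As the list was made from genes low in line 75-IV, this does not decide between the explanations.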

How the results depend on the processing

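The spike-in scaling, the use of all probe sets, the signals at 4 times the floor and the simulation with noise of its own for each array were chosen after seeing the data, and the other alternatives beforehand. Among summary values under alternatives, 364 stayed by the rule set for each, 86 moved and 2 reversed. Among named genes 1310 values stayed within the spread between probe sets of a gene, 127 moved, 110 of them under the spike-in scaling, and 1 reversed, and among the lists added later 254 stayed, 30 moved and 4 reversed. Many could not move. With the floor at the 20th or 60th percentile or none, the 172, 127 and 172 named-gene values stayed by construction. Median centring shifts all ratios of a comparison by less than the spread allowed, so its 172 values stayed too. It also leaves percentiles, r and components unchanged. The numbers of values that stayed therefore do not measure robustness. The cause of a move was not tested except where fewer or more genes were counted by construction. The floor sets which genes can be compared. No paired analysis was possible because each group had 1 array.

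Counts of genes at least 2-fold higher and lower are given in the order ppi1 against wild type, line 75-IV against wild type, ppi1 against line 75-IV. With the floor at the 20th percentile they were 223 and 86, 86 and 34, 155 and 113. With the floor at the 60th percentile they were 32 and 26, 9 and 6, 27 and 35. With no floor they were 589 and 351, 381 and 280, 501 and 394. Over all probe sets they were 197 and 153, 90 and 37, 159 and 189. At 4 times the floor they were 24 and 20, 5 and 5, 21 and 28. With a threshold of 1.5-fold they were 312 and 162, 145 and 74, 269 and 193, and with 3-fold 16 and 9, 5 and 0, 8 and 19. Spike-in scaling gave 367 and 12, 16 and 20, 483 and 17. Loess gave 49 and 61, 21 and 8, 39 and 76, and probe sets without a suffix gave 71 and 28, 23 and 5, 45 and 48.

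Spike-in scaling reversed the photosynthesis medians of ppi1 to 0.0925 against wild type and 0.34 against line 75-IV. It gave percentiles of 0.26 and 0.58, which 1 factor per array could change only through the floor and the random draws. It reversed the wider ribosomal list to -0.12 in line 75-IV against wild type and 0.48 in ppi1 against line 75-IV, and the cell wall list to 0.24 and the root-expressed list to 0.16 in the latter comparison. In ppi1 against wild type it moved the photosystem and ribosomal medians to 0.19 and 0.19. In ppi1 against line 75-IV it moved the photosystem, ribosomal and tetrapyrrole medians to 0.38, 0.47 and 0.59. In line 75-IV against wild type it moved the photosynthesis, photosystem, tetrapyrrole and other plastid medians to -0.24, -0.24, -0.36 and -0.44. Median centring moved the last of these to -0.32, and quantile normalization moved the photosystem median of line 75-IV to 0.0573. The photosynthesis percentile of ppi1 against wild type moved to 2.93 with loess and 2.86 without its farthest member. Against line 75-IV it moved to 2.97 with quantile normalization, 2.52 with loess and 2.55 with probe sets without a suffix. AT2G30600 in line 75-IV reversed to 0.14 as the median of its probe sets.

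With the floor at the 20th percentile the covariance of both mutants was 0.117, with 41 genes higher and 2 lower in both, and the components of wild type, ppi1 and line 75-IV were 0.0838, 0.225 and 0.0650. With the floor at the 60th percentile the covariance was 0.0538, 4 genes were higher in both and the ppi1 component was 0.146. With no floor r was 0.43, the covariance 0.452, 214 genes were higher and 102 lower in both, and the components were 0.123, 0.406 and 0.142. The spike-in scaling gave 1 gene lower in both. The simulated covariance was 0.071 with the plain SD, and 0.0631, with an r of 0.388, when each array had its own noise.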

Other observations

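The wider gene lists used here were chosen after the data had been opened, with the coverage of the annotation and the control probe sets seen and no gene's ratio examined. The root-expressed list was chosen after the lowest and highest genes had been seen, and its test was set before its result. Cell wall genes were higher in line 75-IV than in wild type, 10 of 13 measured members, with a median log2 ratio of 0.32 (interval 0.12 to 0.76) at the 99.2 percentile of random lists, and 7 of 13 and a median of 0.14 under the spike-in scaling. The expansin gene EXPA15 had a signal of 60.1 against 28.0, and EXPB1, EXPA4 and EXPA8 had log2 ratios of 0.87, 0.81 and 0.55. In ppi1 against line 75-IV the list's median was -0.42 (interval -0.89 to 0.51; 0.24 under the spike-in scaling) at the 0.21 percentile, and in ppi1 against wild type 0.14 at the 61.2 percentile, which loess turned to -0.02. Among 50 measured genes of cytosolic ribosomal proteins, which include the 5 of the fixed list, 40 were lower in ppi1 than in line 75-IV, with a median of -0.18 at the 0.39 percentile and 0.48 under the spike-in scaling. In line 75-IV against wild type the same list had a median of 0.06 at the 99.6 percentile and -0.12 under the spike-in scaling, and in ppi1 against wild type -0.16 at the 6.32 percentile and 0.32.

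The cold and dehydration genes as a list had a median of -0.20 in ppi1 against wild type (interval -1.38 to 0.25; 0.28 under the spike-in scaling) at the 7.02 percentile, with 6 of 11 members lower. M17, KIN2 and LTI30 were lower by 2-fold or more and SRC2 was higher (629.4 against 238.4). In line 75-IV their median was 0.07 (-0.10 under the spike-in scaling) and between the mutants -0.15 (0.51). Further photosynthesis genes outside the fixed lists had a median of -0.08 at the 27.0 percentile in ppi1, 0.14 at the 92.0 percentile in line 75-IV and -0.19 at the 8.1 percentile between the mutants. The spike-in scaling turned these medians to 0.41, -0.03 and 0.39. By the percentiles given, the place of the 13 genes among random lists was not seen in this second list. Further plastid protein genes had medians of 0.15, 0.10 and 0.06 in the same order, the second -0.07 under the spike-in scaling and the third -0.01 after median centring. The ATG8 genes of autophagy had -0.29, -0.04 and -0.29, which the spike-in scaling turned to 0.19, -0.22 and 0.37. Medians of the lists for UDP-glucosyltransferases (-0.07, -0.03, 0.17), auxin response (0.05, -0.07, 0.03), endoplasmic reticulum bodies and lectins (-0.04, 0.10, 0.19) and WRKY factors (0.09, 0.00, 0.21) all lay inside the central 95% of random lists, and 7 of these 12 changed sign under at least 1 scaling.

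Peroxidase and dirigent-like genes among the lowest in ppi1 led to a hypothesis of the present work, that the ppi1 seedlings may have held a smaller share of root, although the peroxidase genes AT5G64120 and AT5G39580 were 2-fold or more higher there. Root-expressed genes outside the named ones lay at the 20.7 percentile in ppi1 against wild type (5 of 10 lower), between the bounds of 2.5 and 25 set beforehand, which decided nothing. In line 75-IV all 11 measured members were higher than in wild type, 10 of 11 under the spike-in scaling, with a median of 0.40 (interval 0.27 to 0.71) at the 99.9 percentile. Between the mutants 8 of 10 were lower in ppi1, with a median of -0.50 at the 0.34 percentile and 0.16 under the spike-in scaling. The cell wall list lay on the same side in both comparisons, but these share the line 75-IV array and are not separate observations. In ppi1 against wild type, without that array, the cell wall median was 0.14 (61.2 percentile) and the root-expressed median -0.05. A difference in tissue share was not separated from one in cell wall genes.

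Separate probe sets of a gene gave ratios that correlated across genes with r = 0.75 (92 genes) between the mutants, against 0.37 (83 genes) for ppi1 and 0.15 (86 genes) for line 75-IV against wild type. Across 80 genes, the log2 gap between the brightest and the dimmest probe set minus its mean on the other arrays had a median of -0.14 in line 75-IV (interval -0.22 to -0.05), a narrower gap. For wild type the median was 0.12 (-0.04 to 0.32) and for ppi1 -0.05 (-0.18 to 0.14). Among probe sets that the annotation does not name, the lowest in ppi1 had 108.9 against 863.1 in wild type, and the lowest in line 75-IV 107.9 against 421.2. The 9 spike-in probe sets had a median log2 ratio of -0.49 in ppi1 and 0.17 in line 75-IV against wild type, and all 9 were lower in ppi1. The 3 brightest had ratios of -0.12, -0.21 and -0.25 in ppi1 against wild type and the other 6 from -0.76 to -0.46, so the spike-in scaling, with 1 factor per array, moved bright genes, most of the photosynthesis list among them, by more than the bright spike-in controls differed. Against line 75-IV the same 3 had -0.44, -0.62 and -0.63.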
